A study of Homo sapiens with 12 samples.

How the data were processed

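The series holds 12 strand-specific paired-end libraries made from total RNA of the human adrenocortical carcinoma cell line H295R, 4 of wild-type cells (WT), 4 of cells with DLK1 knocked down (KD) and 4 of cells that over-express it (OE), numbered as replicates 3 to 6 in each group. The deposited table holds raw counts, whole numbers for each Ensembl gene and library, made with FastQC, HISAT2 1.03, Subread featureCounts and DESeq2 on GRCh38, per the submitters' processing notes. The annotation release, the strand setting, the handling of reads with several matches and whether reads or read pairs were counted are not given in the sources used here. Counts of genes with close paralogs, pseudogenes or an overlapping gene are therefore less certain.

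The table lists 60671 genes. One of them, ANK2, has blank counts and was left out. Another 3 lines name no gene, 1 of them a line of totals, and stayed out of library sizes and tests. Names were taken from the table (40582 genes) and coordinates from GENCODE release 29 (58452 genes found). Where several genes share a name, the one with the most counts kept it. The other 1197 were kept apart by their Ensembl identifiers. Library sizes were 9303266 to 13797397 counts.

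Genes were tested with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr by group (minimum count 10, minimum total 15), TMM normalisation, estimateDisp, a robust quasi-likelihood fit of all 12 libraries with 9 residual degrees of freedom, and quasi-likelihood F tests. Of the genes, 15916 passed the filter. The common biological coefficient of variation was 7.38%. Each comparison (KD against WT, OE against WT, OE against KD, and KD plus OE minus 2 times WT) was adjusted over all genes tested by the method of Benjamini and Hochberg, and genes under an adjusted p of 0.05 were called. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM values are counts scaled by TMM-adjusted library sizes. A fold against a group with 0 counts was computed with a floor of 3 counts over that group.

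The comparisons, the tests, the alternatives, the rule for named genes and 29 gene lists were fixed before the data were examined. The lists are steroid synthesis, adrenocortical identity and ACTH response, cholesterol synthesis and uptake, the Hedgehog pathway, Wnt beta-catenin targets, the Notch pathway and its targets, adrenal capsule and progenitor markers, imprinted genes, the IGF axis, ERK feedback targets, immediate early genes, S phase, G2 and M phase, p53 targets, the interferon response, the unfolded protein and integrated stress response, hypoxia and glycolysis, nuclear genes of oxidative phosphorylation, the mitochondrial genome, cytosolic ribosomal proteins, replication-dependent histones, mesenchymal and matrix genes, epithelial genes, adipogenic genes, ABC and efflux transporters, and markers of chromaffin and neuroendocrine cells, fibroblasts, endothelial cells and immune cells. Some genes stand in more than 1 list, and DLK1 was left out of all. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Members were also counted after adjustment over the list alone.

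The genes named are DLK1, the 12 highest and 12 lowest called genes by log2 fold change in KD and in OE against WT, the 6 highest and 6 lowest in OE against KD, up to 4 members of each list with the smallest adjusted p in a comparison, and the 6 genes with the largest smaller fold change among those called in both comparisons with opposite directions and with the same direction. The first 3 groups were limited to protein-coding genes with a mean log2 CPM of at least 0 and no overlap between the libraries compared. From these the text names those that show each group best. A gene named for 1 comparison is also given in others. MIR196A2, its relatives and HOXC6 stand outside the rule.

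On simulated counts with the depth and spread of these libraries and 50 changed genes at each fold, the test found 30%, 76%, 86% and 96% of genes changed 1.2-fold, 1.5-fold, 2-fold and 3-fold in KD against WT, 38%, 76%, 84% and 100% in OE against WT, and 30%, 72%, 88% and 100% in OE against KD. It called 10, 14 and 9 unchanged genes among 15469, 15446 and 15444. A list planted at 1.2-fold was found in all 3, and 0, 1 and 1 of the 28 other lists were called. The single changed genes were drawn from those with a mean of at least 1 CPM. Genes were simulated independently of each other, so false calls of lists with correlated members were not tested. The estimated correlation was 0.883 for the mitochondrial genome list.

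The overlap of KD and OE calls was set beside that of independent lists, that of 20 simulations of unchanged groups, and that with 2 WT libraries for each comparison in all 6 assignments. In the simulations all libraries, WT included, were drawn from a common mean per gene, and both comparisons shared the simulated WT libraries. Libraries were also regrouped: 35 splits of the 8 libraries of each comparison, and 100 groupings of all 12. Runs of neighbouring genes were sought as the running median of log2 fold changes over 51 genes among 15754 genes placed on chromosomes, with 1000 shuffled gene orders. The alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, median-of-ratios size factors or library sizes alone in place of TMM, no filter or at least 10 counts in every library of a group, the replicate number as a block, each library left out in turn, only the 2 groups compared in the fit, and a log2 fold change of at least 1. Offsets for GC content and transcript length (15771 genes, 99.1%), a fit without mitochondrial genes and counts of calls outside the shifted runs were added after the data were seen.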

Results

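H295R is an established human adrenocortical carcinoma cell line that makes steroid hormones. Total RNA from unmodified cells (WT), from cells in which the gene DLK1 was knocked down (KD) and from cells made to over-express it (OE) was sequenced as strand-specific paired-end libraries. The stated purpose was to compare the transcriptomes of these cells at different levels of DLK1. Each group held 4 libraries, numbered as replicates 3, 4, 5 and 6. In that order the gene counts summed to 10725147, 10584491, 12164240 and 9303266 in WT. The sums were 13058210, 11817544, 12458449 and 11597523 in KD, and 10480678, 11633259, 12572969 and 13797397 in OE. Between 22032 and 23235 genes had at least 1 count in a library, and 15916 genes passed the filter on low counts and were tested. The first principal component of the log2 CPM held 17.1% of the variance and the second 12.9%. On it KD libraries lay at 15.47 to 30.92, WT libraries at -11.2 to -1.82 and OE libraries at -18.57 to -14.21. Every pair of libraries within a group differed by more than the sampling noise of independent counts. The chi-square per degree of freedom was 2.73 to 3.55 in WT, 2.83 to 3.94 in OE and 3.82 to 4.24 among KD replicates 4, 5 and 6, but 6.19 to 11.1 for the pairs with KD replicate 3. If both reads of a pair were counted, counts are not independent and sampling noise alone gives values above 1, so the size of the excess is uncertain. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

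DLK1 (ENSG00000185559, GRCh38 chromosome 14, 100725705 to 100738224), an imprinted gene for a transmembrane protein related to Notch ligands, followed the group labels in every library. Its level was 2675 ± 132 CPM (counts scaled for library size; mean ± SD, n = 4) in WT, 1338 ± 113 in KD and 3213 ± 148 in OE. The libraries ranged from 2490 to 2796 in WT, from 1238 to 1487 in KD and from 3020 to 3350 in OE, with no overlap between groups. DLK1 fell by 1.00 ± 0.05 on the log2 scale (± standard error) in KD against WT (edgeR quasi-likelihood test, adjusted p = 4.07e-09). It rose by 0.26 ± 0.05 in OE against WT (adjusted p = 0.00693), a fold of 1.2, and by 1.26 ± 0.05 in OE against KD (adjusted p = 1.43e-10). The transcripts counted could come from the cell's own gene or from a construct, which the counts cannot separate.

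**Figure D1:**
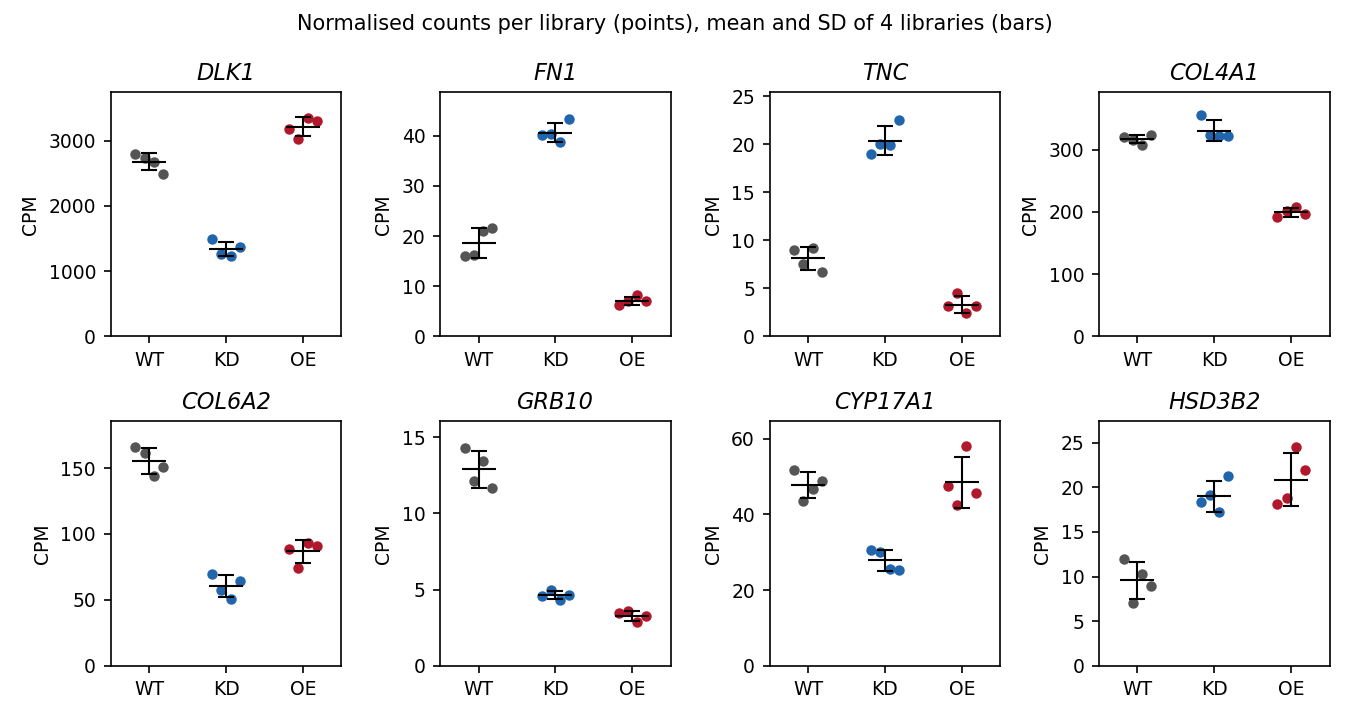
CPM, counts scaled for library size (vertical axes, from 0), of 8 genes in the 4 WT, 4 KD and 4 OE libraries, with points for libraries and black bars for the mean and SD. DLK1 lay at 2490 to 2796 CPM in WT, 1238 to 1487 in KD and 3020 to 3350 in OE, while FN1 and TNC were highest in KD and lowest in OE, and GRB10 was lower in both KD and OE than in WT.

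The comparison of KD with WT asked which genes differ when DLK1 is lowered. TNC, which encodes the matrix glycoprotein tenascin C, rose from 8.13 ± 1.17 to 20.4 ± 1.53 CPM (mean ± SD, n = 4; log2 fold change 1.32 ± 0.15, adjusted p = 1.84e-09). FN1, for fibronectin, rose by 1.12 ± 0.11 (adjusted p = 1.9e-11). COL6A2, for a chain of collagen VI, fell by 1.36 ± 0.08 (adjusted p = 2.57e-13). NOTCH3, for a Notch receptor, fell by 1.24 ± 0.16, and ELOVL2, for a fatty acid elongase, fell by 2.37 ± 0.28. In steroid synthesis, CYP17A1, for the 17-hydroxylase and 17,20-lyase needed for cortisol and androgens, fell from 47.8 ± 3.48 to 27.9 ± 2.79 CPM (adjusted p = 6.3e-09). HSD3B2, for a dehydrogenase of the same pathway, rose from 9.55 ± 2.06 to 19 ± 1.72 CPM (adjusted p = 4.42e-07).

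Among the other genes with the largest changes between KD and WT, FUT1, for a fucosyltransferase, rose by 2.27 ± 0.49 and ANGPTL1 by 1.84 ± 0.44, both from levels under 1 CPM in WT. THBD, for thrombomodulin, rose by 1.45 ± 0.35, ASS1, for argininosuccinate synthase, by 1.26 ± 0.11 and CD36, for a fatty acid and lipoprotein receptor, by 1.18 ± 0.06. ASS1 has many processed pseudogenes and HSD3B2 a close paralog, HSD3B1, so their counts are less certain. CACNA1B, for a neuronal calcium channel subunit, changed by -1.60 ± 0.19, GRB10, for an adaptor of insulin signalling, by -1.48 ± 0.17, LPL, for lipoprotein lipase, by -1.37 ± 0.25 and SCARA5, for a scavenger receptor, by -1.65 ± 0.36. Adjusted p-values in the edgeR test ranged over these genes from 7.25e-21 for CD36 to 0.00386 for THBD.

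Of the 29 gene lists, 9 were called in KD against WT by the camera test with a preset correlation of 0.01, and 0 with an estimated correlation (7 at an unadjusted p under 0.05). For every called list in the 3 comparisons the p with an estimated correlation was the highest over all alternatives run for it. The fry test called all 9 lists in KD against WT. Genes of cholesterol synthesis and uptake were on the higher side, with 7 of 24 measured members higher and 0 lower (10 and 2 adjusted over the list alone; adjusted p = 0.00675, and adjusted p = 0.144 with an estimated correlation). MVD, for mevalonate diphosphate decarboxylase, rose by 0.36 ± 0.06, and DHCR7, for the last enzyme of the pathway, by 0.22 ± 0.04. Of the Wnt and beta-catenin targets, 7 of 19 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.000541, and adjusted p = 0.105 with an estimated correlation). LGR5, a receptor for R-spondins, rose by 0.84 ± 0.12 and BMP4, a secreted growth factor, by 0.68 ± 0.05, while WNT4, a Wnt ligand of the adrenal cortex, fell by 0.27 ± 0.05. In the S phase list 8 of 43 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 0.000541, and adjusted p = 0.183 with an estimated correlation), including the replication factors PCNA (0.25 ± 0.04), MCM5 (0.24 ± 0.05) and CDC45 (0.31 ± 0.07).

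Among ERK feedback targets, 2 of 15 rose and 0 fell in KD (the same counts adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.123 with an estimated correlation), and ETV4, an ETS transcription factor, rose by 1.15 ± 0.18. Of the immediate early genes 3 of 17 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.000541, and adjusted p = 0.112 with an estimated correlation). These were BTG2 (0.55 ± 0.14), JUNB (0.32 ± 0.09) and NR4A1 (0.18 ± 0.06), and these calls were lost without 1 library: BTG2 without WT replicate 4 (adjusted p = 0.0578), JUNB without WT replicate 6 or KD replicate 6 (0.095 and 0.0644), NR4A1 without WT replicate 3 or 4 or KD replicate 4 or 6 (0.0906, 0.0989, 0.0523 and 0.0723), and all 3 without KD replicate 3 (0.0521 to 0.0755). Without that library 0 of the 17 were called, although the list was (adjusted p = 0.00861). With all libraries kept, the NR4A1 call was also lost with GC and length offsets (edgeR, adjusted p = 0.0757). Chromaffin and neuroendocrine markers had 2 of 12 higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.0094, and adjusted p = 0.105 with an estimated correlation). CHGB, for the granule protein secretogranin 1, rose by 0.92 ± 0.08 and SYP, for synaptophysin, fell by 0.33 ± 0.08, so the measured markers did not move together.

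On the lower side in KD were the imprinted genes, with 7 of 27 lower and 1 higher (9 and 2 adjusted over the list alone; adjusted p = 0.0153, and adjusted p = 0.105 with an estimated correlation). GRB10 was among them. PLAGL1, a zinc finger transcription factor, fell by 0.27 ± 0.04 and PEG10, a retrotransposon-derived gene, by 0.26 ± 0.03. The exception was the non-coding RNA H19, with 0, 4, 3 and 2 counts in WT, 58, 38, 37 and 48 in KD and 2, 6, 8 and 7 in OE (log2 fold change in KD 4.04 ± 0.49, adjusted p = 2.15e-08). Mesenchymal and matrix genes had 9 of 30 lower and 4 higher (12 and 6 adjusted over the list alone; adjusted p = 0.0153, and adjusted p = 0.163 with an estimated correlation), and the adjusted p was 0.051 without KD replicate 4 and 0.0791 with no filter. LAMC1, for a laminin chain, fell by 0.59 ± 0.04, against the rises of TNC and FN1.

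Transcripts of the mitochondrial genome had a median log2 fold change of -0.321 in KD, with 4 of 15 lower and 0 higher (10 and 0 adjusted over the list alone; adjusted p = 2.08e-08, and adjusted p = 0.277 with an estimated correlation). MT-ATP8, for a subunit of ATP synthase, fell by 0.56 ± 0.09 and the ribosomal RNA MT-RNR1 by 0.34 ± 0.06. Counts from the mitochondrial genome made up 7.93% ± 0.298 of a library (SD, n = 4) in WT, 6.57% ± 1.11 in KD and 7.31% ± 0.176 in OE, and 4.99% in KD replicate 3. Without that library the median was -0.204 and 12 of the 15 were lower (adjusted p = 1.26e-09).

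The other 20 lists were not called in KD against WT, at adjusted p of 0.0548 to 0.924. Among them, 2 of 17 steroid synthesis genes were higher and 5 lower (3 and 5 adjusted over the list alone), STAR, for the protein that carries cholesterol into mitochondria, among the lower with a log2 fold change of -0.61 ± 0.04 and AKR1C3 among the higher with 0.43 ± 0.07. Of 23 genes of adrenocortical identity and ACTH response 2 were higher and 6 lower (2 and 7 adjusted over the list alone), SOAT1, for a cholesterol-esterifying enzyme, at -0.29 ± 0.04. Median, mean and test differed in sign for 5 uncalled lists. The adrenal capsule and progenitor markers had a median of 0.041 and a mean of 0.175 with a test direction of lower, and the hypoxia and glycolysis list 0.011 and -0.03 with lower. The unfolded protein and integrated stress response had -0.067 and 0.002 with lower, the epithelial genes -0.091 and 0.022 with lower, and the fibroblast markers -0.085 and 0.12 with lower.

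In all, 611 genes were higher and 831 lower in KD than in WT at an adjusted p under 0.05, among them 38 higher and 44 lower by at least 1 on the log2 scale. With library sizes alone in place of the normalisation factors 967 were higher and 624 lower, so that the share of higher genes among those called moved from 42.4% to 60.8%. Without WT replicate 6, 407 were higher, and without KD replicate 3, 482 were higher and 754 lower.

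The comparison of OE with WT asked which genes differ when DLK1 is raised. Of 30 mesenchymal and matrix genes 15 were lower and 1 higher (camera, adjusted p = 9.78e-12). FN1 fell from 18.7 ± 2.98 to 7.11 ± 0.834 CPM (mean ± SD, n = 4; log2 fold change -1.39 ± 0.13, edgeR adjusted p = 5.36e-12). VCAN, for the proteoglycan versican, fell by 1.41 ± 0.15 (adjusted p = 3.96e-06) and COL4A1, for a basement membrane collagen, fell from 317 ± 6.66 to 199 ± 6.65 CPM (adjusted p = 1.63e-17). Of 24 genes of cholesterol synthesis and uptake 10 were higher and 1 lower (camera, adjusted p = 2.22e-05, and adjusted p = 0.0598 with an estimated correlation), INSIG1, a sterol-responsive regulator, at 0.36 ± 0.04 (adjusted p = 6.02e-10). This list was on the higher side in KD as well. In OE against KD it was not called (median log2 fold change 0.01, camera, adjusted p = 0.45), so as a set it did not follow the level of DLK1. Of 17 steroid synthesis genes 4 were higher and 1 lower (4 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.216). HSD3B2 rose from 9.55 ± 2.06 to 20.9 ± 2.95 CPM (adjusted p = 2.08e-08) and STAR fell by 0.26 ± 0.04 (adjusted p = 4.06e-05), so that STAR was lower than in WT in both KD and OE. STAR lies in the runs of shifted chromosome 8 genes described below, whose medians were -0.209 in OE and -0.256 in KD. Its fall in OE was close to that of these neighbours.

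The mesenchymal and matrix genes had a median log2 fold change of -0.263 in OE, with 16 lower and 1 higher adjusted over the list alone. The list was called with the preset correlation (camera, adjusted p = 9.78e-12) and with an estimated one (adjusted p = 0.00452 with an estimated correlation). Besides FN1 and COL4A1, COL4A2 fell by 0.50 ± 0.04, LAMC1 by 0.45 ± 0.04, COL6A2 by 0.84 ± 0.08 and TNC by 1.30 ± 0.18. Of 6 fibroblast markers, some of which the matrix list also holds, 1 was lower and 0 higher in OE (the same counts adjusted over the list alone; mean log2 fold change -0.266, adjusted p = 0.216). Adjusted over the list alone, 11 genes of cholesterol synthesis and uptake were higher and 1 lower, FDPS, for farnesyl diphosphate synthase, at 0.25 ± 0.05.

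Outside the lists, the largest falls in OE were in GAL, for the neuropeptide galanin (-2.59 ± 0.39, from 3.12 ± 0.459 CPM), RASGRP3, for an activator of Ras proteins (-2.04 ± 0.23), MAMDC2 (-1.96 ± 0.39), and UNC5C, for a netrin receptor (-1.91 ± 0.25). SFRP1, for a secreted Wnt antagonist, fell by 1.56 ± 0.07 and EDNRA, for an endothelin receptor, by 1.51 ± 0.19. The largest rises included HRK, for a BH3-only protein (1.18 ± 0.25), TSPAN11 (1.17 ± 0.19), NME4, for a mitochondrial nucleoside diphosphate kinase (1.15 ± 0.13), and SPINT1, for a serine protease inhibitor (1.12 ± 0.23). Adjusted p-values in the edgeR test ran from 8.16e-23 for SFRP1 to 0.00133 for HRK. Some of these genes shifted the same way in KD, by counts not scaled for library size. SPINT1 had 18, 35, 32 and 28 in WT and 78, 58, 70 and 52 in KD. NME4 had 103, 91, 104 and 66 in WT and 175, 176, 169 and 170 in KD. SFRP1 had 1038, 992, 1225 and 853 in WT and 631, 586, 530 and 569 in KD. UNC5C fell in KD too, as given below. GAL stayed similar, with 28, 39, 35 and 29 in WT and 36, 34, 28 and 25 in KD.

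Another 5 lists were called in OE against WT with the preset correlation and not with an estimated one. Of these, fry called ERK feedback targets (adjusted p = 0.0196) and p53 targets (0.0166). Of all 29 lists 7 were called, and 4 without WT replicate 5. ERK feedback targets had 3 of 15 higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.0461, and adjusted p = 0.258 with an estimated correlation), ETV4 at 1.01 ± 0.18 and ETV5 at 0.36 ± 0.07. This call was lost without WT replicate 4, 5 or 6 (adjusted p = 0.0821, 0.0782 and 0.0723), without KD replicate 3 (0.0501) and without OE replicate 3, 5 or 6 (0.0866, 0.116 and 0.0521). It was also lost with the replicate number as a block (0.0783), library sizes alone (0.0679), no filter (0.0539), GC and length offsets (0.0639) and without mitochondrial genes (0.052). ERK feedback targets were on the higher side in KD too, and in OE against KD the list was not called (camera, adjusted p = 0.614). Of 24 p53 targets 2 were higher and 0 lower (3 and 0 adjusted over the list alone; adjusted p = 0.0144, and adjusted p = 0.215 with an estimated correlation), namely CDKN1A, for the cell cycle inhibitor p21 (0.35 ± 0.06), and CCNG1 (0.31 ± 0.05). Its adjusted p was 0.0518 without WT replicate 5 and 0.0723 without WT replicate 6. Cytosolic ribosomal proteins had 9 of 77 lower and 0 higher (18 and 1 adjusted over the list alone; adjusted p = 0.000361, and adjusted p = 0.562 with an estimated correlation), RPS16 at -0.22 ± 0.04 and RPL38 at -0.28 ± 0.06. With fry the adjusted p was 0.206.

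Nuclear genes of oxidative phosphorylation had 4 of 43 lower and 0 higher in OE (4 and 0 adjusted over the list alone; adjusted p = 0.0177, and adjusted p = 0.562 with an estimated correlation), and the adjusted p was 0.0698 without WT replicate 3, 0.0537 without WT replicate 5, 0.136 without OE replicate 5, 0.0639 with GC and length offsets and 0.24 with fry. The mitochondrial genome list was called lower (median -0.163; adjusted p = 0.00302, and adjusted p = 0.562 with an estimated correlation) although 0 of its 15 transcripts were called by edgeR, also adjusted over the list alone (2 at an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 4). With fry its adjusted p was 0.295. The same list was lower in KD than in WT as well.

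The other 22 lists were not called in OE against WT, at adjusted p of 0.056 to 0.987. Among them, 3 of 13 genes of the IGF axis were lower and 1 higher (3 and 1 adjusted over the list alone), with IRS2, for an insulin receptor substrate, at -0.31 ± 0.04 and its relative IRS1 at 0.39 ± 0.09. Of 27 imprinted genes 2 were higher and 1 lower (3 and 1 adjusted over the list alone), PLAGL1 at 0.36 ± 0.04 and GRB10 at -1.97 ± 0.18. Of 19 Wnt and beta-catenin targets 0 were higher and 2 lower (the same counts adjusted over the list alone), APCDD1, for a Wnt inhibitor, at -0.34 ± 0.04 and WNT4 at -0.21 ± 0.05. Median, mean and test differed in sign for the Notch pathway (-0.003 and -0.003, test direction higher), hypoxia and glycolysis (-0.006 and 0.024, higher), S phase (0.01 and -0.006, lower), adipogenic genes (-0.035 and -0.087, higher), chromaffin and neuroendocrine markers (0.045 and -0.004, higher) and immune cell markers (0.024 and 0.024, lower).

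In all, 339 genes were higher and 457 lower in OE than in WT, 20 and 42 of them by at least 1 on the log2 scale. With library sizes alone 487 were higher and 369 lower, so that the share of higher genes moved from 42.6% to 56.9%. With only the WT and OE libraries in the fit 534 were higher and 702 lower.

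The comparison of OE with KD sets the lowest level of DLK1 against the highest. TNC (log2 fold change -2.62 ± 0.16, adjusted p = 1.47e-18), FN1 (-2.51 ± 0.12, adjusted p = 2.8e-23) and ADGRG1, for an adhesion G protein-coupled receptor (-2.27 ± 0.15, adjusted p = 1.66e-17), were among the genes with the largest falls from KD to OE (edgeR, n = 4 libraries a group). CYP17A1 rose by 0.80 ± 0.09, PAPSS2, for the synthase of the sulfate donor used by sulfotransferases, by 0.91 ± 0.09 and SULT2A1, for the enzyme that sulfates DHEA, by 0.61 ± 0.07 (adjusted p = 1.37e-09, 1.18e-10 and 9.55e-09). NLRP2, for an inflammasome-related protein, rose by 1.57 ± 0.21.

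In OE against KD 8 lists were called, of which fry called 6. Of 17 steroid synthesis genes 7 were higher and 2 lower in OE than in KD (7 and 2 adjusted over the list alone; camera, adjusted p = 0.0432, and adjusted p = 0.218 with an estimated correlation). This call was lost without WT replicate 3 or 6 (adjusted p = 0.0503 and 0.0587), without KD replicate 5 or 6 (0.0704 and 0.0571), without OE replicate 5 or 6 (0.0653 and 0.0662) and with the replicate number as a block (0.064). STAR was among the higher at 0.35 ± 0.04 and AKR1C3 among the lower at -0.39 ± 0.07. Of 27 imprinted genes 9 were higher and 1 lower (10 and 3 adjusted over the list alone; adjusted p = 0.00353, and adjusted p = 0.114 with an estimated correlation), with PLAGL1 at 0.63 ± 0.04 and PEG3, a zinc finger gene, at 0.50 ± 0.06, and with H19 at -2.93 ± 0.42. Wnt and beta-catenin targets had 5 of 19 lower and 0 higher (6 and 0 adjusted over the list alone; adjusted p = 0.00348, and adjusted p = 0.182 with an estimated correlation), BMP4 at -0.54 ± 0.05 and LGR5 at -0.75 ± 0.12.

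In the S phase list 12 of 43 were lower and 0 higher in OE than in KD (17 and 1 adjusted over the list alone; adjusted p = 0.00135, and adjusted p = 0.218 with an estimated correlation), CDC45 at -0.44 ± 0.07. In the G2 and M phase list 12 of 54 were lower and 2 higher (17 and 3 adjusted over the list alone; adjusted p = 0.00867, and adjusted p = 0.218 with an estimated correlation), the tubulin gene TUBB4B at -0.25 ± 0.04 and the kinesin gene KIF20B at 0.35 ± 0.06. Of 77 cytosolic ribosomal proteins 21 were lower and 1 higher (21 and 1 adjusted over the list alone; adjusted p = 3.37e-05, and adjusted p = 0.607 with an estimated correlation), RPSA at -0.24 ± 0.03 and RPLP0 at -0.24 ± 0.04. With fry the adjusted p was 0.0662.

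Chromaffin and neuroendocrine markers had 3 of 12 lower and 1 higher in OE than in KD (3 and 1 adjusted over the list alone; adjusted p = 0.0277, and adjusted p = 0.182 with an estimated correlation), CHGB at -0.84 ± 0.08. The adjusted p was 0.0616 without KD replicate 5 and 0.0538 with GC and length offsets. Transcripts of the mitochondrial genome had 2 of 15 higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.00353, and adjusted p = 0.695 with an estimated correlation), and without KD replicate 3, the library with 4.99% of mitochondrial counts, the median was 0.034 and the adjusted p 0.125. With fry the adjusted p was 0.192.

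The other 21 lists were not called in OE against KD, at adjusted p of 0.0565 to 0.791. Of 30 mesenchymal and matrix genes 5 were higher and 8 lower (5 and 9 adjusted over the list alone; adjusted p = 0.0638), COL6A2 at 0.52 ± 0.08 against COL4A1 at -0.73 ± 0.04. Median, mean and test differed in sign for hypoxia and glycolysis (-0.052 and 0.054, test direction higher) and for fibroblast markers (0.009 and -0.386, lower), of which 2 of 6 were lower and 0 higher (the same counts adjusted over the list alone; adjusted p = 0.57). In all, 1157 genes were higher and 1043 lower in OE than in KD, 47 and 77 of them by at least 1 on the log2 scale, and without KD replicate 3 the counts were 1005 and 796.

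Genes that follow the level of DLK1 would move in opposite directions in KD and OE. TNC (1.32 ± 0.15 in KD and -1.30 ± 0.18 in OE), FN1 (1.12 ± 0.11 and -1.39 ± 0.13), ADGRG1 (1.13 ± 0.14 and -1.14 ± 0.16) and ASS1 (1.26 ± 0.11 and -0.68 ± 0.12) did so. In the other direction, PLAGL1 fell by 0.27 ± 0.04 in KD and rose by 0.36 ± 0.04 in OE, and SOAT1 fell by 0.29 ± 0.04 and rose by 0.16 ± 0.04. SOAT1 lies in the run of shifted chromosome 1 genes described below, whose median was -0.191 in KD and -0.076 in OE. DLK1 itself changed far less in OE than in KD, whereas TNC, FN1 and ADGRG1 changed about as much or more in OE. Their changes were therefore not in proportion to that of DLK1, and opposite directions alone do not show that a gene follows its level. Other genes moved the same way in both. GRB10 fell by 1.48 ± 0.17 in KD and by 1.97 ± 0.18 in OE, NOTCH3 by 1.24 ± 0.16 and 1.32 ± 0.16, UNC5C by 1.23 ± 0.24 and 1.91 ± 0.25, and LPL by 1.37 ± 0.25 and 1.25 ± 0.25, while HSD3B2 rose by 0.99 ± 0.14 and 1.13 ± 0.14, and ETV4 by 1.15 ± 0.18 and 1.01 ± 0.18.

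In total 55 genes, DLK1 among them, were called in both comparisons with opposite directions, 20 of them higher in KD and 35 lower in KD, and 217 with the same direction, 69 higher and 148 lower. With offsets for GC content and length 334 genes had the same direction. Independent lists of these sizes would share 35.2 and 36.9 genes. In 20 simulations of unchanged groups, with shared WT libraries that were simulated too, at most 1 gene was called in a comparison. They therefore give no overlap to set beside these counts, and they do not carry the actual deviations of these WT libraries. The log2 fold changes of KD and OE had a correlation across genes of 0.383, against 0.499 to 0.53 in the simulations, and a covariance of 0.0372, against a simulated median of 0.0248, a difference of 0.0124. Genes are not independent replicates. With 2 WT libraries used for KD and the other 2 for OE, 84 to 107 genes moved the same way over the 6 assignments (independent lists 7.99 to 16.2) and 21 to 55 opposite ways (independent lists 7.06 to 15.3). The correlation was then 0.046 to 0.099 and the covariance 0.0062 to 0.0127. The count of opposite genes was 32 without WT replicate 5, 33 without WT replicate 3, 34 without WT replicate 4 and 35 without OE replicate 6.

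A direct test of departure from equal and opposite changes (KD plus OE minus 2 times WT, edgeR) called 867 genes, 351 above and 516 below. DLK1 itself departed by -0.74 ± 0.09 (adjusted p = 8.44e-05), so this test does not part genes that follow the level of DLK1 from others. SFRP1 departed by -2.60 ± 0.12 (adjusted p = 2.72e-23), GRB10 by -3.46 ± 0.29 (adjusted p = 2.84e-13) and HSD3B2 by 2.11 ± 0.24 (adjusted p = 8.58e-09). For TNC the value was 0.02 ± 0.32 (adjusted p = 0.988) and for ADGRG1 -0.01 ± 0.24 (adjusted p = 0.99). The count was 553 without WT replicate 5 and 561 without WT replicate 3.

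**Figure D2:**
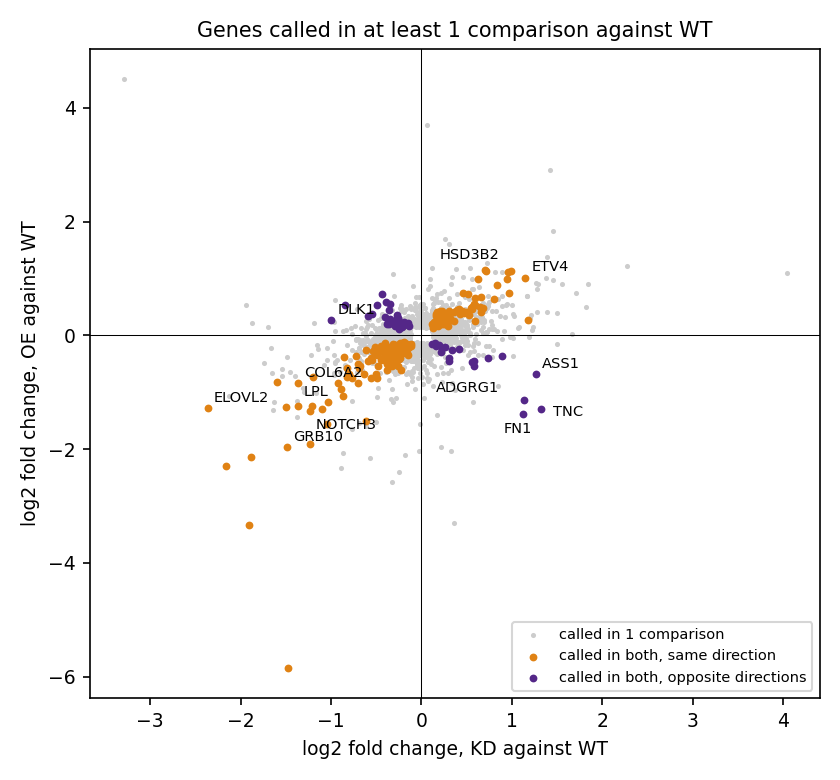
Log2 fold change in KD against WT (horizontal axis) and in OE against WT (vertical axis) of each gene called in at least 1 of the 2 comparisons, with MIR196A2 left out. Orange points are the 217 genes called in both with the same direction, purple points the 55 called in both with opposite directions and grey points those called in 1, and TNC, FN1 and ADGRG1 lie at the lower right.

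MIR196A2 (ENSG00000207924, GRCh38 chromosome 12, 53991738 to 53991847), a microRNA gene of 110 bp in the HOXC cluster, had 1616 to 2167 counts in each KD library and 0 in every WT and OE library. It was chosen after its values were seen. Over the 4 KD libraries its rate was 149 CPM of the unadjusted library totals, at least 2130-fold higher than the 0.0701 that a floor of 3 counts over the WT group allows on that scale. Among relatives, MIR196A1 had 4 to 17 counts in every library and MIR196B had 0. The gene lies within HOXC6 on the same strand, and HOXC6 had 82, 71, 86 and 53 counts in WT and 114, 109, 113 and 63 in KD. Of the 8 tested genes within 100 kb 0 were called in KD against WT by edgeR, by DESeq2 or by limma-voom (0 at an unadjusted p under 0.05 in edgeR), and their log2 fold changes ran from -0.567 to 0.226.

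Changes were also uneven along the chromosomes. Over 51 neighbouring tested genes, the largest median shift in KD against WT was -0.404 on the short arm of chromosome 8, against at most 0.2 in 1000 shuffled gene orders, and in OE against WT it was -0.269 on the same arm, against at most 0.162. In KD, runs beyond every shuffled order covered chromosome 1 from 166856510 to 185291765 (94 genes, median -0.191) and chromosome 5 from 73626158 to 138575724 (251 genes, -0.225). They also covered chromosome 8 from 232137 to 39105144 (167 genes, -0.256) and chromosome 20 from 270863 to 25231933 (124 genes, 0.222). In OE they covered chromosome 8 from 232137 to 38383461 (161 genes, -0.209) and chromosome 19 from 34359480 to 37488652 (76 genes, -0.132). Of the genes called in KD, 218 (15.1%) lay in the KD runs, and of those called in OE, 35 (4.4%) lay in the OE runs. The runs of KD and OE together held 712 genes (4.47% of those tested), and the OE runs alone, with 161 and 76 genes, a smaller share. Of the 796 genes called in OE, 716 lay outside the runs of both comparisons. Of the genes named here, ANGPTL1, SOAT1 and LAMC1 lie in the chromosome 1 run, VCAN in that of chromosome 5, LPL, SCARA5 and STAR in that of chromosome 8, and PCNA, CHGB and THBD in that of chromosome 20.

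**Figure D3:**
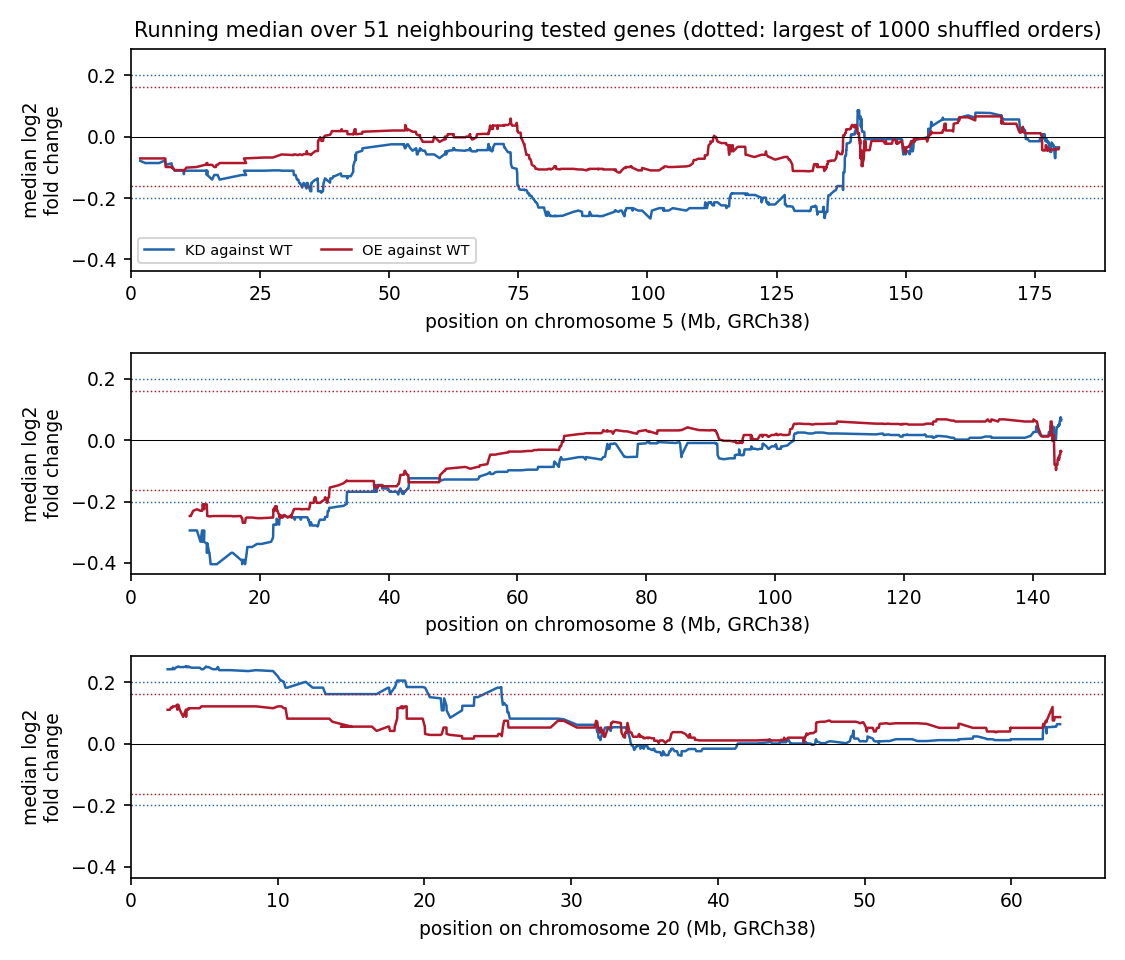
Running median of log2 fold changes over 51 neighbouring tested genes (vertical axis) along chromosomes 5, 8 and 20 (horizontal axis, position in Mb on GRCh38), with KD against WT in blue and OE against WT in red. Dotted lines mark the largest value of 1000 shuffled gene orders, 0.2 for KD and 0.162 for OE, and much of the short arm of chromosome 8 lies below them in both.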

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

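In this part, the explanation of MIR196A2 by a construct, that of the mitochondrial genome by KD replicate 3 and that of the genes changed in the same direction by chromosome runs were chosen after the result was seen. The offsets for GC content and length were added after the data were seen, with their prediction written before the ratio they give was computed. In 14 of 270 groups of 4 libraries 1 library lay far from the other 3 (Dixon's ratio of gap to range, at its 95% bound), and chance alone gives about 1 in 20 groups. The 10 genes with the most counts held 7.937% of the counts of WT replicate 5, against 7.351% to 7.442% in the other WT libraries. In KD, CPM were 33.53 in replicate 4 for ASS1 (others 41.11 to 42.35), 355.2 in replicate 3 for COL4A1 (321.9 to 322.8), 18.18 in replicate 3 for NES (14.93 to 15.42), 44.63 in replicate 3 for TRIB3 (35.71 to 36.56), 5.407 in replicate 6 for HOXC6 (8.638 to 9.137) and 146.3 in replicate 5 for RPL38 (117.6 to 122). In OE they were 0.2901 in replicate 6 for EGLN3 (2.056 to 2.385), 3.409 in replicate 6 for ELOVL2 (2.099 to 2.238), 6.89 in replicate 6 for SPINT1 (5.423 to 5.534) and 36.67 in replicate 4 for IRS1 (39.09 to 39.37). In WT they were 3.682 in replicate 5 for HRK (1.913 to 2.176), 4.069 in replicate 3 for LPL (6.856 to 7.114) and 6.983 in replicate 4 for NLRP2 (4.57 to 4.77).

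MIR196A2 had counts in the 4 KD libraries and in no other. Transcription of the whole HOXC locus would raise its neighbours, but the tested genes within 100 kb had a median log2 fold change of -0.168, so that explanation is set aside. Transcription of MIR196A2 by itself need not raise these genes, so this test cannot decide on it. Sequence carried by the knock-down construct could give such counts, and all 4 KD libraries had counts while WT and OE had 0, as that explanation needs. Since that explanation was found from these counts, they cannot test it, and the construct's sequence was not used here. No biological explanation other than transcription of the whole locus was tested.

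Genes that changed in the same direction in KD and OE against WT were 217, against 36.9 for independent lists. With separate WT libraries for KD and OE, which share no WT noise, the ratio of these 2 numbers had a median of 9.4 (6.23 to 11). In the same assignments the ratio was 2.53 to 3.59 for genes with opposite directions. Without any 1 WT library the ratio was 7.34 or more, and with offsets for GC content and length it was 5.72 (334 genes). Outside the shifted chromosome runs it was 5.64 (163 genes against 28.9). An excess over independent lists thus remained in each case. Its size cannot be compared between them, since it also rose from 5.88 to 6.8 to 7.08 when 1 OE library was left out. Independent lists treat all genes as equally easy to call, so part of each ratio may come from that. With separate WT libraries the ratio stayed above that of opposite genes, so noise of shared WT libraries is not the whole cause. The runs, with 4.47% of the genes tested, still held 54 (24.9%) of the 217 genes. A response to any change of DLK1 and a difference between unmodified and engineered cells (transduction, selection or passage) could both give such genes, and the design, which has no engineered control, cannot part them.

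Transcripts of the mitochondrial genome were lower in KD than in WT, and KD replicate 3 had the lowest share of them. Without that library the median log2 fold change was -0.204 and the list stayed called (adjusted p = 1.26e-09), so it is not the whole cause, although the median with it was -0.321. The call was lost with an estimated correlation (adjusted p = 0.277), and an effect of DLK1 on these transcripts could not be parted from a shared difference in RNA handling.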

How the results depend on the processing

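No test in this part was chosen after the result was seen, except the offsets for GC content and length, the fit without mitochondrial genes and the calls outside the chromosome runs. DLK1 kept its directions and calls under every alternative tool, normalisation, filter, block, offset and choice of libraries or genes (log2 fold change -1.054 to -0.964 in KD, 0.229 to 0.291 in OE). No named gene or list reversed while called under the alternatives run for it. Lists were not run with DESeq2, limma-voom, median-of-ratios size factors, the filter of at least 10 counts, only the 2 groups compared or genes outside the runs. The threshold of 1 on the log2 fold change was applied to counts of genes only, and DLK1 in OE lies under it. The counts below moved by over 1.5 times at 1 alternative or more, and the cause was not tested except where fewer libraries or a stricter threshold explain it. In KD against WT 967 genes were higher with library sizes alone and 407 without WT replicate 6, against 611 in the main analysis. The highest count without 1 library was 725, without KD replicate 5, a smaller move. In OE against WT 534 were higher and 702 lower with only the 2 groups in the fit. With a log2 fold change of at least 1, 38 were higher and 44 lower in KD, 20 and 42 in OE and 47 and 77 in OE against KD, with 3 in both opposite, 15 in both the same and 163 off equal and opposite changes. Over the fits without 1 library, opposite genes ran from 32 (WT replicate 5) to 65 (KD replicate 5, a smaller move from 55) and genes off equal and opposite changes from 553 (WT replicate 5) to 990 (KD replicate 3, a smaller move from 867). There were 334 same-direction genes with GC and length offsets. These offsets kept 1222 of the 1442 genes called in KD against WT and 778 of the 796 in OE against WT. In OE against KD they kept 1696 of 2200, although 2189 genes were called with them. Across genes, log2 fold changes had a Spearman correlation with GC content of 0.181 in KD and -0.06 in OE against WT. Called lists were 0, 1 and 0 with an estimated correlation, 14 in KD with fry, and in OE 4 without WT replicate 5, with up to 8 without KD replicate 5 (7 in the main analysis). At this depth 30% to 38% of 1.2-fold changes were found on simulated data.

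With the replicate number as a block, 557 genes were higher and 770 lower in KD, 313 and 422 in OE and 1102 and 980 in OE against KD. Same-numbered libraries had correlations of -0.033 to 0.071, and 4 of 12 matched their own number best, so the numbers do not pair the libraries.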

Other observations

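The tests in this part that were chosen after the result was seen are named where they stand. In KD against WT, lists that were not called still held members that changed in the edgeR test. Of 28 genes of the unfolded protein and integrated stress response 4 were higher and 2 lower (4 and 6 adjusted over the list alone; camera, adjusted p = 0.447), TRIB3, for a pseudokinase, at 0.65 ± 0.09. Of 27 hypoxia and glycolysis genes 2 were higher and 3 lower (2 and 4 adjusted over the list alone; adjusted p = 0.923), PKM, for pyruvate kinase, at 0.19 ± 0.03 and EGLN3, for an oxygen-sensing hydroxylase, at -1.49 ± 0.36. Of 15 adipogenic genes 4 were higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 0.0548), CD36 at 1.18 ± 0.06 against LPL at -1.37 ± 0.25. Of 10 adrenal capsule and progenitor markers 2 were higher and 2 lower (the same counts adjusted over the list alone; adjusted p = 0.924), NES, for nestin, at 0.68 ± 0.14 and ALDH1A1 at -0.20 ± 0.04. Epithelial genes had 1 of 8 higher and 1 lower (1 and 2 adjusted over the list alone; adjusted p = 0.447), KRT18 at 0.89 ± 0.24 and DSP, for desmoplakin, at -0.41 ± 0.06. Of 12 ABC and efflux transporters 2 were higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 0.798), the cholesterol exporter ABCA1 at 0.72 ± 0.12. Of 25 genes of the Notch pathway NOTCH3 was lower and 1 was higher (the same counts adjusted over the list alone; adjusted p = 0.798). Of 13 genes of the IGF axis 1 was higher and 0 lower (1 and 4 adjusted over the list alone; adjusted p = 0.593), IRS1 at 0.47 ± 0.09.

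Of 54 genes of G2 and M phase 4 were higher and 2 lower in KD against WT (8 and 3 adjusted over the list alone; adjusted p = 0.312), HMMR at 0.30 ± 0.06. Of 24 p53 targets 4 were higher and 0 lower (6 and 2 adjusted over the list alone; adjusted p = 0.119), AEN at 0.29 ± 0.07. Of 77 cytosolic ribosomal proteins 6 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.269), RPL6 at 0.18 ± 0.04, and of 43 nuclear genes of oxidative phosphorylation 0 were higher and 2 lower (the same counts adjusted over the list alone; adjusted p = 0.266), COX7C at -0.32 ± 0.06. In the Hedgehog pathway, the interferon response and the replication-dependent histones edgeR called 0 of 14, 0 of 27 and 0 of 21 genes (2, 7 and 1 at an unadjusted p under 0.05; 0 in each by DESeq2 and limma-voom; camera, adjusted p = 0.923, 0.0922 and 0.447). Markers of other cell types were few among the genes tested, 6 for fibroblasts, 2 for endothelial cells and 2 for immune cells. EdgeR called 0 of each in KD (2, 1 and 0 at an unadjusted p under 0.05; DESeq2 called 1, 0 and 0, and limma-voom 0 in each; camera, adjusted p = 0.924, 0.202 and 0.447). In OE against WT and in OE against KD edgeR called 0 of the endothelial and 0 of the immune cell markers (0 at an unadjusted p under 0.05; 0 by DESeq2 and limma-voom). TRIB3 lies in the chromosome 20 run and COX7C in that of chromosome 5.

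One hypothesis was that runs of neighbouring genes shifted together because a segment of a chromosome was gained or lost in the cells of a group, with a prediction written before the runs were computed. The prediction was a median beyond 0.3 over 51 genes and beyond every shuffled gene order. In KD against WT the largest median was 0.404 in size, which met both conditions, and a gain or loss in the cultures could account for it, as could a change of regulation along the same segment. In OE against WT it was 0.269, beyond every shuffled order but under 0.3, so the test decided neither way. On chromosome 8 from 232137 to 39105144, 87.4% of the 167 genes were below 0 in KD and 80.8% in OE. DNA copy number was not measured in these libraries.

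The counts of calls were set against other splits of the same libraries. In KD against WT 1442 genes were called, and 1 of 35 splits, the real one, gave as many (highest other 14). In OE against WT 796 were called, with 1 of 35 (highest other 1), and in OE against KD 2200, with 1 of 35 (highest other 1). For these 3 a chance allotment of the libraries to groups is excluded at a share under 0.05. If the libraries of a group came from 1 culture, the splits cannot exclude chance differences between cultures. For the 55 genes called in both with opposite directions 1 of 100 groupings gave as many (highest other 0). For the 217 with the same direction and the 867 that departed from equal and opposite changes it was 2 of 100 (highest others 550 and 1456), again a share under 0.05. The 1 other grouping put the 4 KD libraries together in place of WT and mixed WT with OE, so its counts come from the structure of the samples. Most groupings that mix WT, KD and OE give few or no calls, so little overlap or departure was possible in them. These shares therefore show that the groups differ, and cannot test whether KD and OE calls overlap beyond chance. Of the gene lists 9 were called in KD against WT and 7 in OE against WT, and 2 of 35 splits gave as many in each (highest others 9 and 7), so chance is not excluded for these 2 counts. In OE against KD 8 lists were called, with 1 of 35 (highest other 7), a share under 0.05 by a margin of 1 list. The count was 7 with the replicate number as a block, without mitochondrial genes and without WT replicate 3 or 6, KD replicate 6 or OE replicate 6. All these list counts rest on the preset correlation, and with an estimated one 0, 1 and 0 lists were called in KD against WT, OE against WT and OE against KD.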
